A study of Saccharomyces cerevisiae with 22 samples.

How the data were processed

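Total RNA from Saccharomyces cerevisiae was measured on 22 Affymetrix arrays. Per the labels' protocols, cells were grown in rich medium (YPD) to mid-log phase, cDNA was primed with poly(T), and biotin-labelled cRNA was prepared for the arrays. The groups were taken from the labels: 2 untreated arrays, 2 after heat at 40 °C (30 and 45 min), 2 after 0.8 M KCl (30 and 45 min), and 4 after 0.66 mM hydrogen peroxide (15, 30, 45 and 90 min). Cells held for 45 min in heat or in KCl were moved to the same peroxide dose (4 arrays each, 15, 30, 45 and 90 min) or back to rich medium (2 arrays each, 15 and 45 min). Peroxide given without an earlier stress is called naive, and peroxide after heat or KCl is called heat-primed or osmotic-primed. Each stress and time has 1 array, so the untreated pair is the only repeat. The sources used here do not state whether that pair came from separate cultures.

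The deposited value table holds log2 expression values per probe set, made by the authors with RMA per the submitters' processing notes. The version and settings of RMA were not given in the sources used here. A second deposited table by the authors holds log2 fold changes against time 0, for 5900 of the 10928 probe sets; it was used only as an alternative source of values. Probe sets were joined to genes with the array's annotation table. A total of 5498 probe sets named exactly 1 S. cerevisiae gene, and the brightest probe set was kept for each of the 47 genes with several, which left 5449 genes. Left out of the gene tests were 1746 probe sets naming a gene absent from the S. cerevisiae gene table, 3683 absent from the annotation table, and 1 naming several genes. The values were used without further scaling or filtering. Background was taken as the 95th percentile of the probe sets naming no S. cerevisiae gene. The number of arrays sets the precision.

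Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes), with Benjamini-Hochberg adjustment over the 5449 genes and a threshold of 0.05 on the adjusted p. Errors are limma standard errors on the log2 scale. The stresses against untreated cells used 8 arrays (untreated, and heat, KCl and peroxide at 30 and 45 min) with 1 level per group. The primed and naive peroxide series used 12 arrays with terms for group and time. Peroxide against rich medium after each priming used 8 arrays at 15 and 45 min with terms for group and time. Rich medium after a stress against untreated cells used 6 arrays with 1 level per group. In these fits the spread within a group is the change between times, or the departure of a group difference from a constant over time, plus noise. The p-values measure only the spread between these arrays, since no separate cultures are stated.

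A set of 32 gene lists was fixed for stress responses, protein folding and turnover, ribosomes and translation, metabolism, the cell cycle and cell type. They included the genes of the other mating type, meiosis genes, and the strain's auxotrophic markers as a check. The 31 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists of a comparison. Members past the threshold were counted over all genes and adjusted over the list alone. Of 189 list calls with the preset correlation, 0 held with an estimated correlation, where the smallest adjusted p was 0.0587. Correlations across genes between comparisons that share control arrays were set beside values from 100 simulations with unchanged groups. Genes are not independent replicates in those correlations.

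The groups, comparisons, tests, gene lists and alternatives were chosen before the data were examined. So was the rule for named genes: among genes past the threshold whose difference has the same sign at every matched time (or whose 2 treated arrays both lie beyond both untreated arrays), the 10 largest rises and 10 largest falls were taken for 5 comparisons and 5 each way for the others. The 5 are heat, osmotic and oxidative stress against untreated cells, and each primed series against the naive one. Where no gene passed, the 3 largest differences each way are given as values only. Up to 4 members of each described list with the largest differences could be named as well. Every gene said to have risen or fallen under the first part of the rule showed its direction on all arrays or at all times compared.

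The alternatives were another quantile normalization, arrays shifted to one median, the dimmest 25% of genes left out, a variance model with trend and robust settings, a minimum of 2-fold, the mean of a gene's probe sets, the authors' fold-change table, each array left out, and for some comparisons each time left out, other time terms, or other sets of arrays. The fits were tested on simulated data with 5449 genes, 200 of them changed, in 5 simulated sets. Changes of 1 on the log2 scale were recovered for 86.0% of genes in the primed series, 61.2% in the stresses against untreated cells, 51.6% in peroxide against rich medium and 40.4% in rich medium against untreated cells. False calls per set were 6 to 7.6.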

Results

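The 22 arrays followed budding yeast through a first stress (heat or KCl) and then through peroxide. Beside them were cells that met peroxide directly and cells that went back to rich medium. Array medians over the 5449 genes lay between 10.16 and 10.22 on the log2 scale, and 97.4% to 99.0% of genes were above a background of 4.62. The untreated pair differed with a standard deviation of 0.142, with r = 0.998 across genes and 3 genes more than 2-fold apart. The number of genes at least 2-fold from the untreated mean was 1543 and 1092 on the heat arrays and 1618 and 1702 on the KCl arrays. In naive peroxide it was 251, 773, 489 and 133 at 15, 30, 45 and 90 min. It was 426, 351, 234 and 49 at the same times in heat-primed peroxide, and 738, 659, 371 and 91 in osmotic-primed peroxide. Back in rich medium it was 258 and 97 at 15 and 45 min after heat, and 478 and 113 after KCl. As a sign of RNA quality, the 3′ minus 5′ signal of ACT1 lay between 0.36 and 0.68 on the log2 scale on the 22 arrays. That of SPT15 was 1.71 and 1.62 on the heat arrays and 1.17 to 1.56 on the others, and that of SRB4 was 1.81 and 1.42 on the KCl arrays and at least 1.88 on the others.

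**Figure D1:**
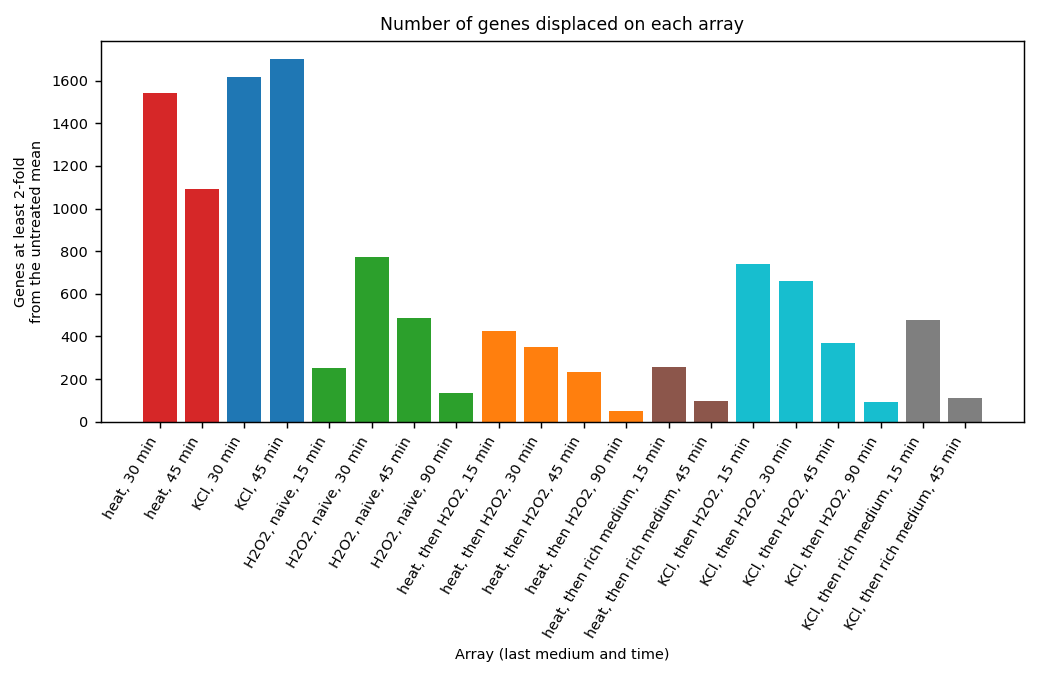
Number of genes at least 2-fold from the mean of the 2 untreated arrays (vertical axis, count), on each of the 20 stressed or recovering arrays (bars). The KCl array at 45 min had the most (1702) and the heat-primed array at 90 min the fewest (49).

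Heat at 40 °C was compared with untreated cells to ask which transcripts the first stress itself moved. The largest rise was that of HSP30, a plasma membrane heat shock protein, at 94.0-fold (log2 6.56 ± 0.79, SE, n = 2 arrays per group). The stress-induced genes TMA10 (log2 6.01 ± 0.27) and DDR2 (5.85 ± 0.20), the cytochrome c isoform gene CYC7 (5.37 ± 0.40) and the aldehyde dehydrogenase gene ALD3 (4.90 ± 0.49) rose with it, as did YER053C-A, RTC3, EGO4, GPM2 and SOL4. The largest fall was that of DBP2, an RNA helicase, at 67.5-fold (log2 -6.08 ± 0.38). The hexose transporter gene HXT2 (-4.57 ± 0.36), the adenine deaminase gene AAH1 (-4.45 ± 0.76) and the nucleolar genes DHR2, NOP7, SDA1 and NSR1 (-4.46, -4.09, -4.05 and -3.87) also fell, as did HO, RKI1 and BSC1. With limma, 1500 genes rose and 1221 fell of 5449 at an adjusted p under 0.05.

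By group, 30 of the 32 measured heat shock chaperone genes rose in heat, 1 fell and 1 did not pass (30 higher and 1 lower adjusted over the list alone). Examples are SSA4, an Hsp70 (log2 4.78 ± 0.28), HSP78, a mitochondrial disaggregase (4.64 ± 0.15), and HSP26, a small heat shock protein (4.39 ± 0.26). Their median was 1.73 (camera adjusted p = 5.95e-11, and adjusted p = 0.453 with an estimated correlation). Of the 36 general stress genes, 35 rose and 1 did not pass, with a median of 3.58 (adjusted p = 1.26e-17, 0.453 as the adjusted p with an estimated correlation; 35 also passed adjusted over the list alone). Of 21 genes of trehalose and glycogen synthesis and breakdown, 19 rose, 1 fell and 1 did not pass, among them PGM2, phosphoglucomutase (4.55 ± 0.26), and TSL1, a trehalose synthase subunit (4.53 ± 0.26). In autophagy and vacuolar proteolysis 26 of 29 rose, including APE1, an aminopeptidase (2.69 ± 0.27). Both lists were called higher (adjusted p = 4.48e-08 and 9.74e-07, and adjusted p = 0.453 for both with an estimated correlation).

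The growth-related groups went the other way in heat. All 96 measured genes of ribosome biogenesis and RNA polymerase I fell, with a median of -2.37 (adjusted p = 4.52e-26, and adjusted p = 0.453 with an estimated correlation). Of 129 cytosolic ribosomal protein genes 64 fell, 1 rose and 64 did not pass, and the same numbers passed adjusted over the list alone. Their median was -0.60 (adjusted p = 6.13e-13, and adjusted p = 0.487 with an estimated correlation). Of 41 translation factor genes 29 fell, of 21 tRNA synthetases 16 fell, and of 34 genes for arginine, lysine and other amino acid synthesis 19 fell and 3 rose. The core histone genes fell in 8 of 9 cases, with HHT1, histone H3, at -1.23 ± 0.16 and HTB2, histone H2B, at -1.14 ± 0.16. In the G1 and S list 18 of 37 fell and 2 rose. In the G2 and M list 14 of 28 fell, among them the cyclin gene CLB2 (-1.14 ± 0.23). In the mating and pheromone list 18 of 26 fell and 4 rose, with FAR1, a cell cycle inhibitor, at -2.72 ± 0.28 and AGA1, an agglutinin subunit, at -2.55 ± 0.14. The camera adjusted p of these 7 lists lay between 4.75e-08 and 0.000399, and with an estimated correlation between an adjusted p of 0.453 and 0.476. Leaving out 1 array moved the 2721 calls of heat against untreated to 1469 (untreated a), 1491 (untreated b) or 1666 (heat at 30 min).

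KCl at 0.8 M was compared with the same untreated cells. STL1, a glycerol symporter, rose 528-fold (log2 9.05 ± 0.27, n = 2 arrays per group). The hexose transporter gene HXT5 (7.40 ± 0.50), the transketolase gene TKL2 (7.05 ± 0.55), the cytosolic catalase gene CTT1 (6.69 ± 0.83) and the proline permease gene PUT4 (6.33 ± 0.23) followed, with PHM7, YNL194C, ALD3, NQM1 and CYC7. The largest falls were mostly in ribosome assembly genes, with RRS1 at -4.91 ± 0.36, NOG1 at -4.71 ± 0.57, RRP12 at -4.63 ± 0.52 and NSR1 at -4.58 ± 0.40, and SYO1, MRD1, ARX1, RRP5, AAH1 and HO were also among the 10 largest. With limma, 1647 genes rose and 1415 fell.

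All 36 general stress genes rose in KCl, with a median of 4.34 (adjusted p = 1.62e-17, and adjusted p = 0.592 with an estimated correlation). Of the 24 osmotic stress and glycerol genes 17 rose, 2 fell and 5 did not pass, with the same counts adjusted over the list alone. SIP18, a hydrophilin, rose by 6.17 ± 0.45 on the log2 scale, and the list's median was 1.12 (adjusted p = 0.000117, and adjusted p = 0.592 with an estimated correlation). Of 32 chaperone genes 18 rose, 2 fell and 12 did not pass, with HSP42 at 4.52 ± 0.21. Of 31 peroxisome and fatty acid oxidation genes 22 rose and 3 fell, with POT1, a thiolase, at 4.45 ± 0.51. The meiosis and sporulation list, markers of a cell type not grown here, held 32 genes that rose, 1 that fell and 10 that did not pass, with SPS100, a spore wall gene, at 6.09 ± 0.32 and IME2, a meiotic kinase, at 2.82 ± 0.36. In ribosome biogenesis 95 of 96 fell, with a median of -2.89 (adjusted p = 1.26e-24, and adjusted p = 0.592 with an estimated correlation). Of 129 cytosolic ribosomal protein genes 19 fell (9 adjusted over the list alone). Leaving out 1 array moved the 3062 calls of osmotic against untreated to 1976 (untreated a) or 2019 (untreated b).

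Peroxide in naive cells was compared with untreated cells at 30 and 45 min, the times shared with heat and KCl. The genes with the largest rises included several redox genes. FRM2, of the nitroreductase family, rose 97.7-fold (log2 6.61 ± 0.25, n = 2 arrays per group). TSA2, a peroxiredoxin (5.83 ± 0.37), SRX1, the sulfiredoxin that repairs peroxiredoxins (5.63 ± 0.55), and OYE3, an NADPH oxidoreductase (5.59 ± 0.25), followed, with DDR2, LSO1, HBN1, RTC3, TMA10 and ECM4. OLE1, the fatty acid desaturase gene, fell most (-3.14 ± 0.18), then IZH4, PLB2, INA1, PHO5, MAE1, GLT1, IZH1, BIO2 and SFG1, down to -1.89. With limma, 610 genes rose and 391 fell.

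Of the 39 oxidative stress defence genes 25 rose in peroxide, 1 fell and 13 did not pass (32 higher and 1 lower adjusted over the list alone), with GTT2, a glutathione transferase, at 4.23 ± 0.34. Their median was 1.01 (adjusted p = 5.2e-15, and adjusted p = 0.317 with an estimated correlation). Of 36 general stress genes 30 rose (32 adjusted over the list alone), with a median of 2.17. In the iron regulon 17 of 28 rose, among them HMX1, heme oxygenase (3.73 ± 0.38), FRE5 (2.78 ± 0.26) and TIS11, an mRNA decay factor (2.76 ± 0.52). Of 42 proteasome genes 10 rose, and 35 were higher adjusted over the list alone. In DNA damage and ribonucleotide reduction 10 of 27 rose and 1 fell, with RNR3, a reductase subunit, at 1.98 ± 0.14. In G2 and M 15 of 28 fell, with ALK1 at -1.47 ± 0.23. In ribosome biogenesis 25 of 96 fell (45 adjusted over the list alone), with a median of -0.97. Camera called these lists with an adjusted p of 0.000371 or less, and with an estimated correlation the adjusted p lay between 0.317 and 0.510. Leaving out 1 array moved the 1001 calls of oxidative against untreated to 125 (untreated a), 154 (untreated b), 215 (peroxide at 30 min) or 612 (45 min). Taking 15 and 30 min in place of 30 and 45 min gave 198, and taking all 4 times gave 0 (983 at an unadjusted p under 0.05, limma). Fitting all 22 arrays together, which also takes in all 4 peroxide times, gave 4.

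Across genes, the heat and KCl responses had r = 0.83, heat and peroxide 0.73, and KCl and peroxide 0.71, where unchanged groups sharing the untreated arrays gave a simulated r of 0.50 each time. The covariances were 1.16, 0.557 and 0.643 against simulated values of 0.0321, 0.0323 and 0.0323. Heat and KCl shared 1057 genes that rose (453 for independent lists) and 860 that fell (317), while 55 went opposite ways (759). Part of the excess may come from the shared untreated arrays, although their simulated covariance of 0.0321 was small beside the 1.16 of heat and KCl. Tested directly, heat was higher than KCl for 838 genes and lower for 830. HSP30 was 17.5-fold higher in heat (log2 4.13 ± 0.79, n = 2 arrays per group), the cell separation gene DSE4 13.3-fold, the phosphate transporter gene PHO84 11.2-fold, and the copper transporter gene CTR1 and NCA3 followed at 9.33-fold and 9.18-fold. STL1 was 398-fold lower in heat than in KCl (log2 -8.64 ± 0.27), with PUT4, the mitochondrial pyruvate carrier gene MPC3, FMP48 and SPS100 between -6.07 and -4.59.

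Of 32 chaperone genes 16 were higher in heat than in KCl and 16 did not pass (18 higher adjusted over the list alone), with a median of 0.68 and AHA1, an Hsp90 co-chaperone, at 1.84 ± 0.17. The list had an adjusted p of 6.91e-06, and adjusted p = 0.486 with an estimated correlation. Of 66 mitochondrial ribosomal protein genes 30 were higher and 1 lower. In cell wall genes 13 of 36 were higher and 3 lower, with PST1 at 3.06 ± 0.27, and in the unfolded protein response and ER folding list 10 of 25 were higher and 1 lower, with ERO1, an ER oxidase, at 1.64 ± 0.15. The core histones were lower in heat for 7 of 9 (median -0.69), and the peroxisome list for 12 of 31 with 2 higher. These 5 lists had a camera adjusted p of at most 0.0208, and with an estimated correlation the adjusted p was at least 0.394. Without the heat array at 45 min, heat against osmotic gave 848 calls in place of 1668.

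**Figure D2:**
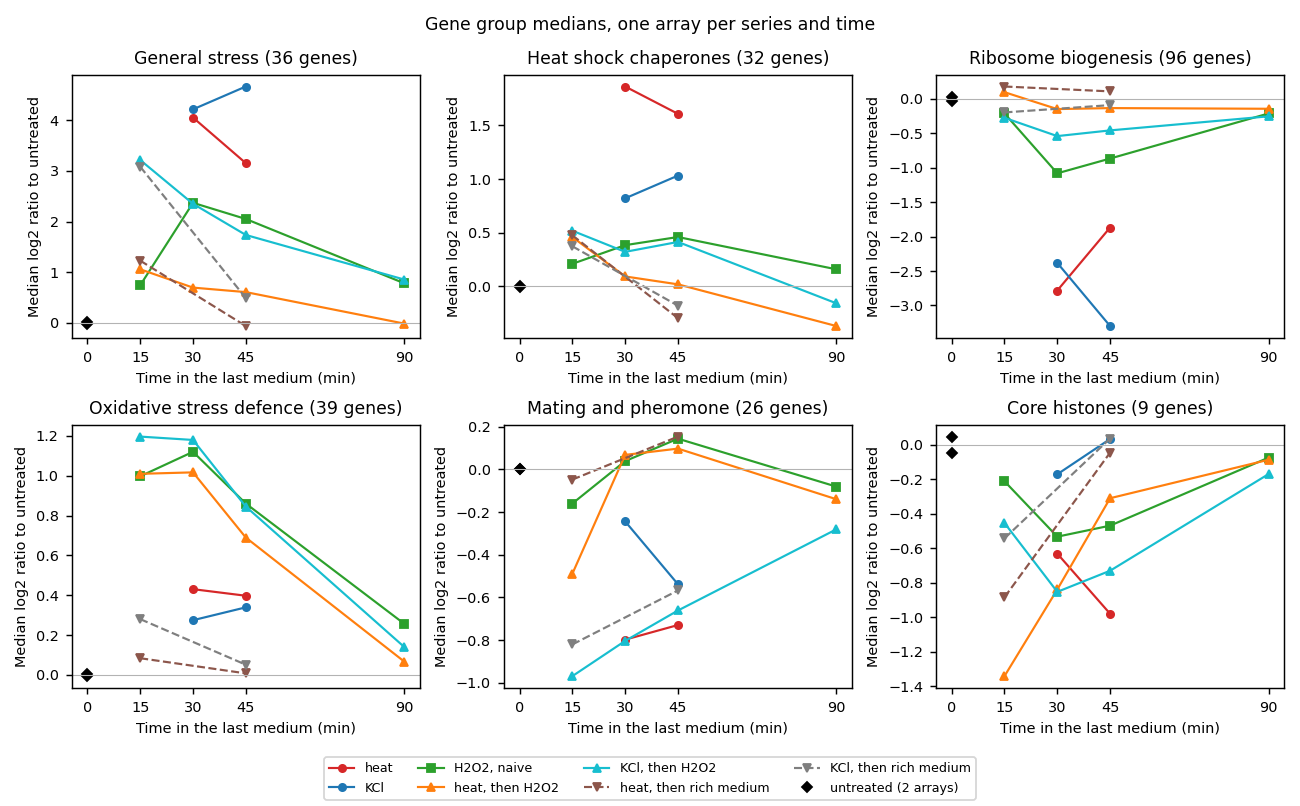
Median log2 ratio to the untreated mean (vertical axes) of 6 gene groups against the time in the last medium (horizontal axes, min), with 1 point per array and lines joining the arrays of a series. The general stress median was 4.67 in KCl at 45 min and 0.61 in heat-primed peroxide at 45 min, and the oxidative stress defence medians of the 3 peroxide series were at least 0.69 from 15 to 45 min.

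Cells returned to rich medium were compared with untreated cells to see what remained of the first stress. After heat, 0 genes passed with limma, where 288 had an unadjusted p under 0.05 and chance gives 272. The largest differences were those of HSP12, a membrane-protecting heat shock protein (log2 3.39 ± 0.44, n = 2 arrays per group, adjusted p = 0.693), GPG1 (3.06 ± 0.81) and HSP26 (2.82 ± 0.96), and on the low side WSC4, RSB1 and TPO1 (-2.91, -2.05 and -1.62). After KCl, 0 genes passed with limma and 405 had an unadjusted p under 0.05. STL1 was at 5.67 ± 0.79 (adjusted p = 0.290), and the transaldolase gene NQM1 at 5.63 ± 0.86, with TKL2 next, against FRE7, PLB2 and IZH4 at -2.83, -2.81 and -2.50. Without the 45 min array of rich medium after KCl, rich medium after osmotic stress against untreated gave 195 genes.

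The general stress median was 1.23 at 15 min and -0.06 at 45 min after heat, and 3.08 and 0.49 after KCl. Over both times after KCl it was 1.77 (camera adjusted p = 1.35e-20, and adjusted p = 0.723 with an estimated correlation), with 0 members past the threshold over all genes and 2 adjusted over the list alone. In the mating and pheromone list the median after KCl was -0.63 (adjusted p = 3.04e-11, and adjusted p = 0.581 with an estimated correlation), with 12 of 26 lower adjusted over the list alone and 0 over all genes. AGA2 was at -1.65 ± 0.34, FUS1 at -1.32 ± 0.15 and AGA1 at -1.22 ± 0.15. After heat, ribosome biogenesis had a median of 0.14 (adjusted p = 5.64e-06, and adjusted p = 0.998 with an estimated correlation) with 0 members passing. Heat shock chaperones, at 0.48 at 15 min after heat, were at -0.29 at 45 min. Simulations of rich medium after heat against untreated recovered 40.4%, 75.6% and 89.2% of changes of 1, 2 and 3 on the log2 scale, which does not by itself account for the large differences that did not pass. In this fit the change between both times counts as spread.

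Heat-primed and naive cells in peroxide were compared at 4 matched times, to ask what an earlier heat stress changed in the later response. The genes with the largest falls included several of protein folding. HSP30 was 7.78-fold lower (log2 -2.96 ± 0.35, n = 4 arrays per group, adjusted p = 0.0118), BTN2 and CUR1, which sort misfolded proteins, were at -2.01 ± 0.24 and -2.00 ± 0.21, and HSP78 and SIS1, an Hsp40, at -1.79 ± 0.20 and -1.67 ± 0.17. The phosphate transporter gene PHO89 was 5.83-fold higher (2.54 ± 0.45), and GSC2, a glucan synthase subunit, was at 1.14 ± 0.17. DBP7, an RNA helicase of ribosome assembly, was at 1.02 ± 0.15 and RRN11, an RNA polymerase I factor, at 0.89 ± 0.15. The other genes named by the rule were DAL1, IZH1, COA2, JJJ3, GFD2 and OPT2, from 1.40 to 0.89, and YER053C-A, TPO4, GLC3, IMD2 and XKS1, from -2.06 to -1.42, where the IMD2 probe set is of a kind that can match related genes. With limma, 84 genes were higher and 98 lower.

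In the chaperone list 9 of 32 genes were lower in heat-primed cells and 23 did not pass (15 lower adjusted over the list alone). The median was -0.44 (camera adjusted p = 1.43e-06, and adjusted p = 0.717 with an estimated correlation). The difference came from the later times: the list median against untreated cells at 15, 30, 45 and 90 min was 0.46, 0.09, 0.02 and -0.37 in heat-primed cells, and 0.21, 0.38, 0.46 and 0.16 in naive cells. Of 96 ribosome biogenesis genes 13 were higher and 83 did not pass, while 86 were higher adjusted over the list alone, and all 96 had a positive difference. SPB1 was at 0.87 ± 0.16 and RCL1 at 0.81 ± 0.13, and the median was 0.51 (adjusted p = 4.75e-27, and adjusted p = 0.717 with an estimated correlation). In naive cells the median of this list against untreated cells was -1.08 at 30 min, and in heat-primed cells it was -0.15 at that time. That heat-primed array had a 25S ribosomal RNA signal of 7.46, against 5.43 or less on the other arrays of its series. In autophagy and vacuolar proteolysis 6 of 29 were lower, with APE1 at -1.18 ± 0.19 (13 lower and 2 higher adjusted over the list alone). The general stress list had a median of -0.94 and the proteasome list of -0.26, with 0 members past the threshold in either, over all genes or adjusted over the list alone. Against untreated cells, general stress was at 1.06 in heat-primed and 0.74 in naive cells at 15 min, and lower in heat-primed cells at the later times (0.70 against 2.37 at 30 min). In the iron regulon 2 of 28 were lower, with ARN2, a siderophore transporter, at -1.37 ± 0.26, and in DNA damage PHR1, photolyase, and PLM2 were lower (-1.28 ± 0.27 and -1.22 ± 0.26). The oxidative stress defence list, by contrast, had 1 of 39 lower and a median of -0.07 (adjusted p = 0.377), and CTT1 was at -1.25 ± 0.70 without passing. The autophagy, general stress, proteasome and iron lists were called with a camera adjusted p of at most 0.00108, and adjusted p = 0.717 with an estimated correlation.

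The count rested on the times and arrays included. Of the 182 calls in heat-primed against naive oxidative stress, leaving out the 30 min time gave 0 (708 at an unadjusted p under 0.05, limma), the 45 min time 1, and the 90 min time 749. Leaving out 1 naive array gave 393 (15 min), 1 (30 min), 2 (45 min) or 829 (90 min), and 1 heat-primed array 9, 1, 1 or 721 at those times. Quantile normalization gave 261 higher and 179 lower, and the values from the authors' fold changes gave 199 higher and 134 lower.

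**Figure D3:**
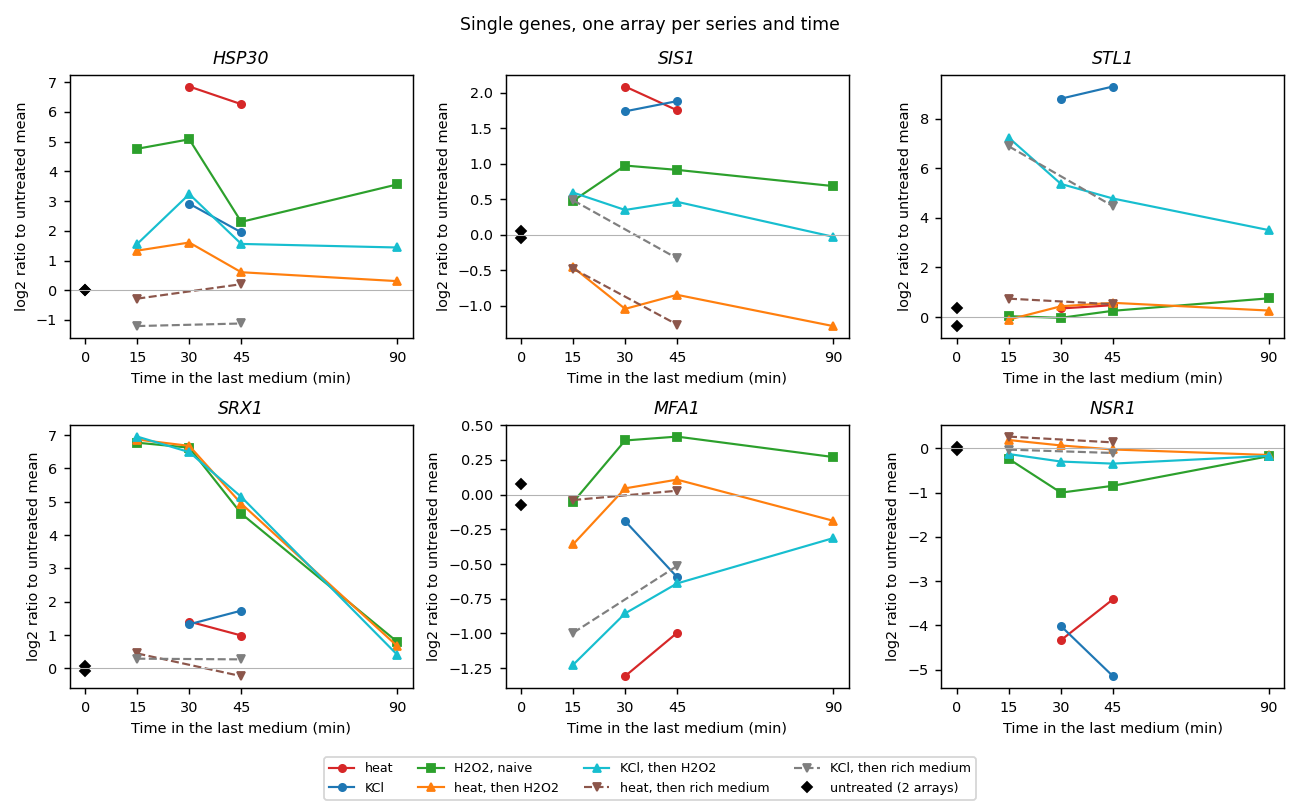
Log2 ratio to the untreated mean (vertical axes) of 6 genes against the time in the last medium (horizontal axes, min), with 1 point per array and lines joining the arrays of a series. SIS1 lies lower in heat-primed than in naive peroxide at each time (log2 -1.67 over the 4 times), STL1 stays high after KCl in both media, and SRX1 follows nearly the same course in the 3 peroxide series.

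Osmotic-primed cells were compared with naive cells in peroxide in the same way. STL1 was 31.2-fold higher (log2 4.96 ± 0.62, n = 4 arrays per group, adjusted p = 0.0282). MFA1, which encodes the a-factor pheromone, was 2.02-fold lower (-1.01 ± 0.13), and the Ty3 element genes YGR109W-B, YGR109W-A and YIL082W-A were at -1.65 ± 0.23, -1.25 ± 0.15 and -1.08 ± 0.11. PHO11, an acid phosphatase, IMD2 and YFL041W-A were at -1.24, -1.12 and -0.76. The probe sets of YGR109W-A, YIL082W-A, PHO11 and IMD2 can match related genes. These were the 1 higher and 7 lower genes that passed with limma.

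All 26 mating and pheromone genes had a negative difference in osmotic-primed cells. Of these 1 passed over all genes and 25 did not, while 25 were lower adjusted over the list alone, and the median was -0.72 (camera adjusted p = 8.94e-17, and adjusted p = 0.471 with an estimated correlation). AGA2 was at -1.48 ± 0.32, PRM1 at -1.42 ± 0.31 and AGA1 at -1.37 ± 0.28. Of the 4 measured genes of the other mating type, MF(ALPHA)2 was at -1.31 ± 0.28 and STE3 at 0.40 ± 0.14, with 0 passing over all genes (limma). In osmotic stress and glycerol 1 of 24 was higher and 23 did not pass (6 higher adjusted over the list alone), with SIP18 at 3.79 ± 0.91, GRE1 at 3.10 ± 0.91 and GPP2, glycerol phosphatase, at 1.53 ± 0.41. In cell wall genes 0 of 36 passed over all genes, and 7 were higher and 1 lower adjusted over the list alone. General stress had a median of 0.44 and ribosome biogenesis of 0.19, with 0 members passing over all genes in either list. The general stress value rested on 15 min, where the median against untreated cells was 3.22 in osmotic-primed and 0.74 in naive cells; at 30, 45 and 90 min it was 2.35, 1.74 and 0.86 in osmotic-primed cells, and 2.37, 2.05 and 0.78 in naive cells. The camera adjusted p of these 4 lists was at most 0.00513, and with an estimated correlation the adjusted p was 0.471 for cell wall genes and 0.782 for the others. The 8 calls of osmotic-primed against naive oxidative stress became 0 without the 30 min or the 45 min time (376 and 591 at an unadjusted p under 0.05, limma) and 66 without the 90 min time. Leaving out 1 naive array gave 3, 0, 0 or 129 at 15, 30, 45 and 90 min, and leaving out an osmotic-primed array gave 0 for 30 or 45 min and 44 for 90 min. The authors' fold-change table gave 3 higher and 9 lower.

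The 2 priming effects had r = 0.415 across genes, below the simulated r of 0.499 for unchanged groups that share the naive arrays, with a covariance of 0.0479 against a simulated 0.0174. Given separate naive arrays, r was 0.490 with 15 and 45 min for heat priming and 30 and 90 min for osmotic priming. With these times exchanged r was 0.0547. The primings were then at different times as well, so these values do not show the effect of separate arrays alone. Both comparisons called 3 genes lower, where independent lists share 0.126, and part of that excess may come from the shared arrays.

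Heat priming was then compared with osmotic priming directly. The acid phosphatase gene PHO5 was 3.55-fold higher after heat (log2 1.83 ± 0.24, n = 4 arrays per group) and the oligopeptide transporter gene OPT2 2.24-fold. STL1 was 30.4-fold lower (-4.92 ± 0.62), and SIS1 (-1.25 ± 0.17), the coactivator gene MBF1 (-1.07 ± 0.13), YIR042C (-1.06 ± 0.14) and the mitochondrial Hsp40 gene MDJ1 (-0.81 ± 0.10) were lower, each of the 7 with an adjusted p of 0.0378. All 36 general stress genes had a negative difference, with 0 past the threshold over all genes and 16 lower adjusted over the list alone. Their median was -1.29 (camera adjusted p = 4.96e-15, and adjusted p = 0.524 with an estimated correlation). Of 32 chaperone genes 2 were lower and 30 did not pass (10 lower adjusted over the list alone), with a median of -0.46. All 26 mating genes had a positive difference, with 19 higher adjusted over the list alone and 0 over all genes, and a median of 0.56. Both lists were called with an adjusted p of at most 3.92e-08, and adjusted p = 0.524 with an estimated correlation. The 7 calls of heat-primed against osmotic-primed oxidative stress became 1, 0 and 0 without the 15, 30 or 45 min time (426 and 577 at an unadjusted p under 0.05 for the 2 counts of 0, limma) and 56 without the 90 min time. Leaving out 1 heat-primed array gave 0, 0, 0 or 45 at 15, 30, 45 and 90 min, and 1 osmotic-primed array 3, 0, 0 or 44. The authors' fold-change table gave 1 higher and 5 lower.

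Peroxide was compared with rich medium in cells from the same priming, at 15 and 45 min. The aim was to separate the response to peroxide from the return from the first stress. After heat, SRX1 was 55.6-fold higher in peroxide (log2 5.80 ± 0.49, n = 2 arrays per group), FRM2 51.4-fold (5.68 ± 0.38), OYE3 37.7-fold (5.24 ± 0.22), GTT2 13.7-fold (3.77 ± 0.31) and AAD4, an aryl-alcohol dehydrogenase measured by a probe set that can match related genes, 7.80-fold. HES1, of the oxysterol-binding family, was 2.39-fold lower. With limma 8 genes were higher and 1 lower (230 at an unadjusted p under 0.05 in either direction, where chance gives 272). The other 3 higher ones were CCP1, AIF1 and MF(ALPHA)2, an alpha-factor gene of the other mating type (1.97 ± 0.17). With a time term for each medium, oxidative against rich medium after heat gave 32 higher and 0 lower. After KCl 9 genes were higher and 0 lower (400 at an unadjusted p under 0.05 in either direction, limma), led by SRX1 (5.77 ± 0.49), FRM2 (5.37 ± 0.38), OYE3 (4.49 ± 0.22), AAD6 (4.32 ± 0.41) and GTT2 (4.09 ± 0.31), and with a time term for each medium oxidative against rich medium after osmotic stress gave 31 higher and 2 lower. Those beyond the rule, CCP1, AIF1, MF(ALPHA)2, and AAD4 and YLL056C after KCl, were named after their values were seen. Both comparisons called 7 genes higher, with r = 0.84 across genes against a simulated r of 0.00 and a covariance of 0.122 against 0.000191, from separate arrays; independent lists would share 0.0132.

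Of 39 oxidative stress defence genes 4 rose after heat (20 adjusted over the list alone) and 5 after KCl (18 adjusted over the list alone), with medians of 0.74 and 0.73. Camera gave an adjusted p of 2.59e-38 and 2.78e-22, and with an estimated correlation an adjusted p of 0.0587 and 0.131. The iron regulon had medians of 0.41 and 0.63, G2 and M of -0.35 and -0.45, and G1 and S of -0.38 and -0.48, each with 0 members past the threshold over all genes or adjusted over the list alone. The adjusted p of these lists was at most 2.26e-05, and with an estimated correlation the adjusted p was 0.559 after heat and 0.590 after KCl. Tested directly, 0 genes differed between the primings in their peroxide effect (18 at an unadjusted p under 0.05, limma, where chance gives 272), which does not show that the effects were alike. The largest values were YML131W at 2.28 ± 0.59, MF(ALPHA)2 at 1.79 ± 0.24 and PRX1 at 1.60 ± 0.68, and HSP30 at -1.71 ± 0.40, GTO3 at -1.57 ± 0.88 and YKL070W at -1.45 ± 0.90, each with an adjusted p of 1. Chaperones had a median difference of -0.23 (adjusted p = 0.000300, and adjusted p = 0.828 with an estimated correlation). For oxidative stress defence the median was -0.03 while the mean was 0.07 and camera called it higher (adjusted p = 0.0449, and adjusted p = 0.828 with an estimated correlation). The 9 calls of oxidative against rich medium after heat became 0 without the peroxide array at 15 min or at 45 min (440 and 205 at an unadjusted p under 0.05, limma), and 2 or 1 without the rich medium array at 15 or 45 min. Quantile normalization gave 7 higher and 0 lower. The 9 calls of oxidative against rich medium after osmotic stress became 0 without either peroxide array (228 and 244 at an unadjusted p under 0.05, limma), and 1 or 2 without either rich medium array.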

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

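The tests of peroxide dose and the counts over other splits of the arrays were chosen before their results were seen, and the tests of scaling, of levels already low after heat, of the other mating type, of a need for peroxide and of another time were chosen after.

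Some arrays lay far from the rest of their series of 4. Among 24 measures of such series tested by their largest gap (Dixon's test), 3 stood out, where chance gives about 1 in 20, or 1.2 of these. The median of the probe sets that name no S. cerevisiae gene was 3.74 on the heat-primed array at 45 min, with the other 3 at 3.79 to 3.80, and 3.77 on the naive array at 15 min, with the other 3 at 3.73 to 3.74. The 25S ribosomal RNA signal was 7.46 on the heat-primed array at 30 min, against 5.01, 5.09 and 5.43 on the other 3.

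Heat and KCl moved 55 genes in opposite directions (759 for independent lists), with each effect and the difference between them past the threshold. Of these, 36 rose in heat and fell in KCl, led by DSE4 (log2 1.13 in heat and -2.61 in KCl) and NCA3 (2.20 and -0.997), and 19 did the reverse, led by the carbonic anhydrase gene NCE103 (-1.21 and 1.67). The priming stresses differed by a direct test for 7 genes in peroxide. The log2 differences, heat-primed minus osmotic-primed, were 1.83 for PHO5, 1.16 for OPT2, -4.92 for STL1, -1.25 for SIS1, -1.07 for MBF1, -1.06 for YIR042C and -0.81 for MDJ1. The 402 probe sets that have a value in the authors' fold-change table but no gene name here were used in no comparison, and they also responded. Of them 144 passed the threshold in heat, 156 in KCl and 47 in peroxide against untreated cells. Among the 1746 probe sets naming a gene absent from the S. cerevisiae table, 4, 4 and 0 passed (limma).

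For the counts of genes that differ between priming groups, the 8 arrays of each pair of series were divided in all 35 ways into 4 and 4. For heat-primed against naive peroxide, 2 splits gave at least the real 182 genes and the highest other gave 630, so chance cannot be excluded. That split exchanged the naive array at 15 min with the heat-primed array at 90 min, and its count was several times the real one. The opposite exchange, of the naive array at 90 min with the heat-primed array at 15 min, gave 0. The cause of the high count was not tested. For osmotic-primed against naive peroxide, 2 splits gave at least the real 8 genes and the highest other gave 29, so chance cannot be excluded. For heat-primed against osmotic-primed peroxide, 1 split, the real one, gave 7 genes and the highest other gave 0. The arrays are matched by time, and most of the 35 splits mix times. The 8 splits that keep all 4 times on each side are too few for a share under 0.05, and the highest others among them were 2, 0 and 0.

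Over the 4 times of peroxide, chaperone transcripts were lower in heat-primed than in naive cells, with a list median of -0.44, where 9 of 32 members passed over all genes and the list's adjusted p was 0.717 with an estimated correlation. At 15 min the list median against untreated cells was higher in heat-primed cells (0.46 against 0.21), and it was lower at 30, 45 and 90 min. Under the 3 other scalings the median nearest to 0 was -0.40, so the pattern did not depend on the choice among them. A shift of medians could hardly have removed it, since array medians lay between 10.16 and 10.22 before it. A fault that all the scalings share cannot be excluded by them. For the peroxide dose, the 9 genes called between peroxide and rich medium after KCl were compared between heat-primed and naive cells. Their median difference was 0.080 and their mean 0.157, with a standard error of 0.08 over genes, which are not independent replicates. As a set they were thus not lower in heat-primed cells over the 4 times together. A single dose was used, so whether these genes follow the dose is not known. A weaker dose in the cultures moved from heat cannot be excluded. At 90 min alone 8 of the 9 were lower in heat-primed cells, with a median of -0.12. Whether these transcripts are already below their untreated level once heat ends, with or without peroxide, stays open. In rich medium after heat the list median went from 0.48 at 15 min to -0.29 at 45 min, with a single array at each time. A level below untreated cells without peroxide was thus seen at the later time only. In heat-primed peroxide the list median at 15 min, 0.46, was near the 0.48 in rich medium after heat. At 45 min it was above the -0.29 in rich medium. The lower level than in naive cells is therefore not shown to be a change in the response to peroxide.

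Ribosome biogenesis transcripts were less reduced during peroxide in heat-primed than in naive cells, with a list median of the difference of 0.51. Over all genes 13 of 96 members passed, and the list's camera adjusted p was 0.717 with an estimated correlation. Of the other scalings, the one nearest to 0 also gave 0.51, with the same limit as above on what they can exclude. The 9 peroxide genes, at 0.080, cannot exclude a weaker dose here either. The same response moved to another sampled time is argued against, since the lowest median of the 4 heat-primed arrays lay 0.93 above the lowest of the 4 naive ones. A milder loss of ribosome biogenesis transcripts after heat priming is a hypothesis from the same data. The return from heat can be set beside peroxide after heat at 15 and 45 min only, with a single array at each time. In rich medium after heat this list stood slightly above untreated cells, with medians of 0.18 and 0.11 at these times. In heat-primed peroxide the medians were 0.10 and -0.13, so they were lower than in rich medium at both times. In naive peroxide they were -0.21 and -0.87. Whether peroxide lowered this list less after heat than in naive cells was not tested directly. The difference between cultures handled on other occasions was not tested.

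Mating and pheromone transcripts were lower in osmotic-primed than in naive cells, with a list median of -0.72, where 1 of 26 members passed over all genes and the list's adjusted p was 0.471 with an estimated correlation. Under the scaling nearest to 0 the median was -0.63, and the same limit on what the scalings can exclude holds here. Cells of the other mating type in the KCl series would bring the pheromone transcripts of that type. MF(ALPHA)1 and MF(ALPHA)2 rose by at most 0.37 over untreated cells on any of the 6 arrays after KCl, so no such rise was seen. These genes cannot exclude such cells. MF(ALPHA)1 was below the background of 4.62 on every array, so its probe set was not shown to detect them. MF(ALPHA)2 also rose in naive peroxide, so it did not follow cell type alone. Of the other genes of that type, STE3 was 0.40 higher in osmotic-primed than in naive cells and SAG1 was at -0.13, both without passing. On their brightest arrays STE3 and SAG1 reached 8.14 and 8.84 on the log2 scale, above that background. A loss that needs peroxide is argued against by the arrays in rich medium after KCl, where the list median nearer to 0 was -0.57. A lasting effect of KCl on these genes may be the source, as a hypothesis found in the same arrays.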

How the results depend on the processing

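All alternatives named here were chosen before the data were examined. Named genes were mostly chosen for one sign over all arrays or times compared, so leaving out an array could hardly turn one. Of their values under the alternatives, 1463 kept their side of the threshold, 428 were weaker, 6 stronger and 0 reversed in sign. Of the list results under other scalings 543 kept their call, 22 were weaker and 2 reversed, both for meiosis and sporulation genes in oxidative against rich medium after osmotic stress, where the median of 0.20 became -0.10 with quantile normalization and -0.055 with the authors' fold changes (the cause was not tested). Counts stayed within 1.5 times in 113 cases and moved in 77. The 113 include counts of 0 that stayed at 0. The cases also take in the total of list calls and a few correlations, which were judged by another rule. The 0 of the difference of the oxidative effect between primings held throughout, as did that of rich medium after heat against untreated. At an unadjusted p under 0.05 they had 18 and 288 genes (limma), where chance gives 272. The 18 lies far below chance, so a 0 was likely under any setting and its holding says little. At least 97.4% of genes lay above background on every array, so signal over background limits only the dimmest genes, 36 of which were below it on all arrays. Where leaving out an array leaves 1 in a group, that array is assumed to vary like the other groups.

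A minimum of 2-fold, stricter by construction, gave 29 genes for heat-primed against naive oxidative stress, 1292 for heat against untreated, 1604 for osmotic against untreated, 485 for oxidative against untreated and 581 for heat against osmotic. The cause was not tested for the other shifts that follow, except that fewer arrays leave fewer degrees of freedom. For heat-primed against naive oxidative stress (182), quantile normalization gave 440, leaving out the dimmest genes 352, the trend and robust model 312, the authors' fold changes 333, no time term 6, only the 2 groups compared 3, and leaving out the 30, 45 or 90 min time 0, 1 or 749. Single arrays left out gave 1 to 829. For osmotic-primed against naive oxidative stress (8), leaving out the dimmest genes gave 4, no time term 2, only the 2 groups 0, leaving out the 30, 45 or 90 min time 0, 0 or 66, and single arrays 0 to 129. For heat-primed against osmotic-primed oxidative stress (7), leaving out the dimmest genes gave 4, no time term 4, only the 2 groups 2, leaving out the 15, 30, 45 or 90 min time 1, 0, 0 or 56, and single arrays 0 to 45. Single arrays left out gave 1469 to 2530 for heat against untreated (2721), 1976 to 3044 for osmotic against untreated (3062), 125 to 612 for oxidative against untreated (1001) and 848 to 1874 for heat against osmotic (1668). For oxidative against untreated, all 22 arrays in one fit, which also takes in all 4 peroxide times, gave 4. All 4 times gave 0 (983 at an unadjusted p under 0.05, limma), and 15 and 30 min 198. A time term for each medium gave 32 for oxidative against rich medium after heat (9) and 33 for oxidative against rich medium after osmotic stress (9), and single arrays left out 0 to 2 for both. For rich medium after osmotic stress against untreated (0), all 22 arrays in one fit gave 1, and single arrays left out 0 to 195, the highest without the 45 min array. An estimated correlation took the gene list tests from 189 calls to 0. Separate naive arrays, which also put the primings at different times, gave correlations of priming effects of 0.490 and 0.055 in place of 0.415.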

Other observations

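The hypotheses on patterns across the priming series stand with their tests above, and the values here were chosen after they were seen, without a further test. The core histone genes were low early after heat and came back with time. Their median log2 ratio to untreated was -0.98 at 45 min of heat, -0.88 after 15 min back in rich medium and -0.05 after 45 min there. In heat-primed peroxide it was -1.34 at 15 min, -0.84 at 30 min, -0.31 at 45 min and -0.09 at 90 min. After 45 min of KCl it was 0.03, followed by -0.54 and 0.04 at 15 and 45 min in rich medium, and by -0.45, -0.85, -0.73 and -0.17 in osmotic-primed peroxide. The G1 and S list was at -0.51 on the 45 min heat array and at 0.63 after 45 min back in rich medium, and in KCl and then rich medium at -0.99 and 0.37.

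The trehalose and glycogen median was 2.47 at 45 min of heat, 3.56 at 45 min of KCl and 1.63 at 45 min of naive peroxide, and 0.51 and 0.81 at that time in heat-primed and osmotic-primed peroxide. The sulfur amino acid and methionine list was at 0.72 after 15 min in rich medium following heat and at 0.66 after 30 min of heat-primed peroxide, and between -0.26 and 0.29 on the other arrays. Among genes of the other mating type, STE3, the a-factor receptor, rose in heat (1.77 ± 0.17, adjusted p = 0.000370, n = 2 arrays per group), and MF(ALPHA)2 rose in naive peroxide (1.77 ± 0.26, adjusted p = 0.00660). The auxotrophic marker list, meant as a strain check, had medians between -0.30 and 0.27 on the 22 arrays and was called in 0 of the 12 comparisons. These are ratios to untreated cells of the same series, so they cannot show which strain was used.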
